A study of Mus musculus with 8 samples.

How the data were processed

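LEPR+ cells were sorted from collagenase-digested marrow of long bones as live cells without CD45, Ter119, CD31 and CD144, and sorted again into lysis buffer, per the labels' protocols. PolyA RNA was sequenced as paired reads of 76 bp. Groups and replicate numbers were taken from the sample titles, with 4 control and 4 LTβR-Ig libraries. The series' design text speaks of 4 pairs and does not say what a pair shares. The submitters' processing notes name HISAT2, HTSeq and the build mm10. Their versions, the annotation release and the strand setting are not given in the sources used here. The authors deposited 1 matrix of raw counts, whole numbers per gene with no normalization, for 52636 genes and 8 libraries.

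Gene symbols and coordinates came from GENCODE M21 on GRCm38, the assembly also called mm10. Without the version suffix 52403 gene IDs matched, and 49035 matched with it. The IDs without a symbol took between 0.0207 and 0.148% of counts per library. As a check for a library deposited more than once, replicate counts were compared by chi-square over genes, and the values per degree of freedom lay between 153 and 302 for all pairs within a group, so all 8 libraries were kept. Total counts lay between 52378101 and 64403177 per library. Haemoglobin genes took 2.68 ± 1.39 and 2.40 ± 0.834% of counts. Mitochondrial genes took 1.53 ± 0.17 and 1.68 ± 0.234% (SD, n = 4 each).

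Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes were filtered with filterByExpr by group (minimum count 10, minimum total count 15), and dispersions were fitted with estimateDisp and robust glmQLFit. The quasi-likelihood F test compared LTβR-Ig with control on all 8 libraries with no covariate, and p-values were adjusted by Benjamini-Hochberg over 16045 genes, with 0.05 as the threshold. CPM values are TMM-scaled. Standard errors are the size of the log2 fold change divided by the square root of F, and 95% intervals use the fit's degrees of freedom. Tested on simulated counts with the real means and library sizes, the same test called 22% of genes raised 2-fold and 20% of genes lowered to 0.5 of control, and 78 and 70% of those raised 4-fold and lowered to 0.25, among 15331 genes, together with 5 unchanged genes. The changed genes, 50 per fold, were drawn only from genes with a mean above 5 CPM. Genes of the LTβR target list described below were lowered as well. More true changes ease the adjusted threshold, and the real test also held genes with lower counts. These rates may therefore be higher than those of the real test. At this number of libraries most 2-fold changes would be missed.

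Before the data were examined, 33 gene lists were fixed, covering the LTβR pathway, niche and lineage genes, general cell programmes and 12 other cell types. Lists with at least 5 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes, and fry asks whether its genes move one way on balance. The shares of counts taken by the 12 marker lists were compared by exact two-sided permutation with Benjamini-Hochberg adjustment. Many blood markers stem from cells that the gate excludes, and some markers, such as Vcam1, Fabp4 and Ngfr, are also made by LEPR+ cells or stand in another list.

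The naming rule, fixed at the same time, took up to 12 genes per direction past the threshold with a mean log2 CPM of at least 1 and a symbol that is not a predicted locus. Where fewer than 10 passed, as here, it took the 10 genes with the smallest p. It added 26 genes of interest and up to 4 members of each list with the smallest p. The last part was applied only to the 10 lists called with the preset correlation. Of the 26, Madcam1 was not tested because of low counts (22 counts in 1 control library and 0 in the others). Other list members named in the text were chosen after their values were seen. One gene taken by the rule is not reported here.

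Alternatives were DESeq2 size factors and upper-quartile factors in edgeR, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, no filter, and a filter of at least 10 counts in 4 or more libraries with a mean of at least 5 CPM. The replicate number as a block and leaving out each library were also planned. Settings chosen after seeing the data were a marker level as covariate, thinning all libraries to the smallest total, the strict filter with the block, leaving out the 2 libraries at the ends of the first principal component, and estimated correlations under the block and without libraries.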

Results

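The data are gene counts from bulk polyA RNA sequencing of leptin receptor positive (LEPR+) mesenchymal stem cells of mouse bone marrow. These perivascular stromal cells are a main source of the niche factors CXCL12, stem cell factor and IL-7. C57BL/6 mice had received weekly intravenous doses of 150 µg for 3 weeks. One group was given LTβR-Ig, a soluble decoy that binds the ligands of the lymphotoxin β receptor, and the other a control immunoglobulin against hen egg lysozyme. The labels give 4 libraries per group. They do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries. Total gene counts were 61585346, 64403177, 56466028 and 58612111 in control replicates 1 to 4. They were 61164510, 53772597, 57438028 and 52378101 in LTβR-Ig replicates 1 to 4. Between 18383 and 19781 genes were detected per library.

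The comparison asks which genes of LEPR+ cells changed when LTβR signalling was blocked. C3, the central component of complement, fell furthest. It went from 1422 ± 242 CPM (counts scaled by library size) in control libraries to 114 ± 12.7 in LTβR-Ig libraries (SD, n = 4 each), a 12.4-fold difference. Ager, which encodes the receptor for advanced glycation end products, fell 10.4-fold. Meox1, a mesodermal homeobox factor, fell 7.08-fold, the secreted protein gene Angptl1 5.88-fold and the kinase gene Dclk1 4.26-fold. Each of these genes was lower in 4 of 4 LTβR-Ig libraries than in any control library.

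By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 of 16045 genes passed an adjusted p of 0.05, and all 6 were lower with LTβR-Ig. The log2 fold change of C3 (ENSMUSG00000024164.15, chromosome 17, 57203970 to 57228136 in mm10) was -3.64 (SE 0.15, edgeR adjusted p = 3.92e-05). Ager (ENSMUSG00000015452.14, chromosome 17, 34597862 to 34600936) had -3.37 (SE 0.29, edgeR adjusted p = 0.00738). Dclk1 (ENSMUSG00000027797.15, chromosome 3, 55242364 to 55539068) had -2.09 (SE 0.18, edgeR adjusted p = 0.00738). Angptl1 (ENSMUSG00000033544.6, chromosome 1, 156838562 to 156861078) had -2.55 (SE 0.24, edgeR adjusted p = 0.00875). Meox1 (ENSMUSG00000001493.9, chromosome 11, 101877510 to 101894374) had -2.82 (SE 0.27, edgeR adjusted p = 0.00875). The other gene past the threshold was the predicted locus Gm37802 (log2 fold change -2.53, SE 0.27, edgeR adjusted p = 0.019), which lies outside the naming rule and was named after its values were seen. Gm37802 spans 156856217 to 156858859 on chromosome 1, inside Angptl1 and on the opposite strand, so without a stated strand setting its reads cannot be told apart from those of Angptl1. Dclk1 and Meox1 also overlap predicted loci in the annotation.

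No gene was higher past the threshold in the edgeR test, where 544 genes were higher and 470 lower at an unadjusted p under 0.05. DESeq2 called 167 higher and 171 lower, and limma-voom with sample weights called 3 higher and 14 lower. A stricter filter on low counts left 10952 genes and gave 22 calls, 5 higher and 17 lower. The count fell to 2, C3 and Ager, without control replicate 3, and to 1, C3, without both control replicate 3 and LTβR-Ig replicate 2, which lay at the ends of the first principal component. With the replicate number as a block it was also 1, C3. Without control replicate 3 the edgeR adjusted p was 0.0533 for Dclk1 and 0.0621 for Angptl1 and Meox1, and for Meox1 it was 0.0532 without LTβR-Ig replicate 1 and 0.0604 without LTβR-Ig replicate 2. Gm37802 had 0.0528 to 0.103 without each library other than LTβR-Ig replicate 4.

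**Figure D1:**
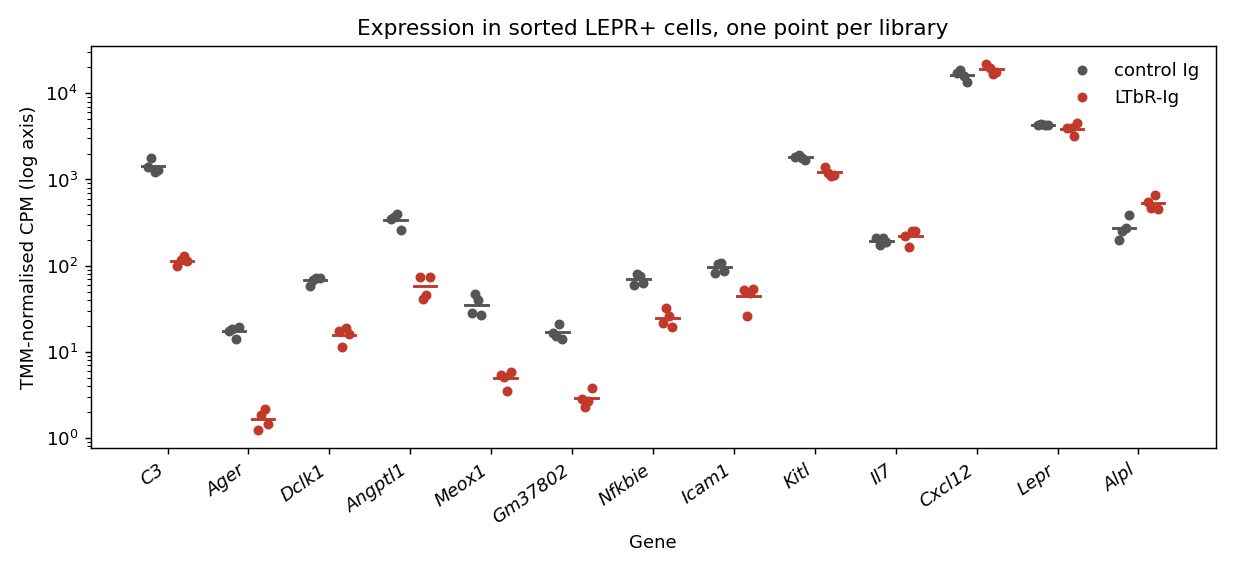
CPM of 13 genes on a log axis, with 1 point per library and a bar at each group mean, in control (grey) and LTβR-Ig (red) libraries. C3 lies at 1422 ± 242 CPM in control and 114 ± 12.7 CPM in LTβR-Ig libraries (SD, n = 4 each), while the points of Il7, Cxcl12 and Lepr overlap between the groups.

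The genes with the next smallest p-values did not pass. Tnc, a matrix glycoprotein, had a log2 fold change of 0.71 (SE 0.09) and Fstl1, a secreted glycoprotein, 0.59 (SE 0.07), both with an edgeR adjusted p of 0.0506. Nfkbie, an inhibitor of NF-κB, had -1.49, the chemokine gene Ccl7 -1.89 and the serpin gene Serpina3g -1.52, each with an edgeR adjusted p of 0.061. DESeq2, limma-voom and the stricter filter called all 5 of these genes. All 5 genes were separated between the groups in 4 of 4 libraries. Chance gives this for a share of 0.0286 of genes in either direction when genes are not picked. These 5 were picked for small p-values in the same data, so their separation adds no support of its own. Serpina3g belongs to a cluster of close paralogs, between which the counting may split reads.

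Genes known as targets of LTβR and NF-κB in stromal cells fell as a group. Of 27 targets tested, 12 were lower and 1 higher when adjusted over the list alone, and none passed over all genes in the edgeR test, where 13 were lower and 1 higher at an unadjusted p under 0.05. The lower 12 included the monocyte chemokine genes Ccl2 (log2 fold change -1.19) and Ccl7 (-1.89), the adhesion molecule gene Icam1 (-1.09) and the non-canonical NF-κB subunit genes Relb (-1.15) and Nfkb2 (-0.83). They also held the feedback inhibitors Nfkbie (-1.49), Nfkbia (-0.64) and Tnfaip3 (-1.33), with Cxcl16 (-1.36), Ccl19 (-1.25), Tnfsf13b (-0.82) and Birc3 (-0.71). The gene higher was Tnfsf11, which encodes the osteoclast factor RANKL, at 1.26. The median over the list was -0.75, and 12 members were lower and 2 higher in 4 of 4 libraries, against a chance share of 0.0286 for both directions. Of the members taken by the naming rule, DESeq2 called Nfkbie, Ccl7, Ccl2, Cxcl16, Ccl19, Relb and Icam1 over all genes. Nfkb2, Tnfsf13b, Birc3, Cxcl13 and Vcam1, also taken by the rule, were not called over all genes in any setting run. DESeq2 results for the members outside the rule, among them Tnfsf11, Nfkbia and Tnfaip3, were not looked up.

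The list test, camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 33 lists, gave an adjusted p of 9.52e-12 for the target list. The list held with an estimated correlation (camera adjusted p = 0.00904) and with fry (adjusted p = 0.00277), and it was the only called list to pass both. With an estimated correlation its camera adjusted p was 0.0567 without LTβR-Ig replicate 2 and 0.246 without both that library and control replicate 3. It was 0.126 with the replicate number as a block.

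**Figure D2:**
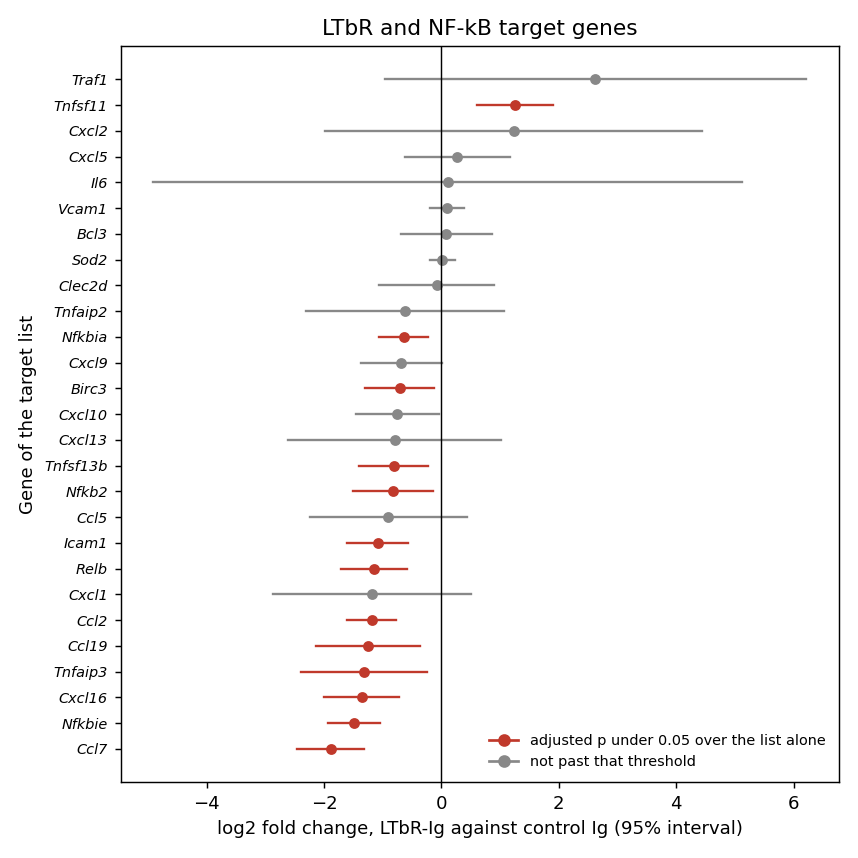
Log2 fold change of the 27 tested target genes, LTβR-Ig against control, with 95% intervals from the edgeR fit (4 libraries per group). Red marks the 12 lower genes and 1 higher gene past 0.05 when adjusted over the list alone, and the lowest estimate is Ccl7 at -1.89.

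Members of the LTβR signalling pathway were lower as a list (median log2 fold change -0.32 over 16 genes, camera adjusted p = 0.0176, adjusted p = 0.344 with an estimated correlation, fry adjusted p = 0.0328). Map3k14, which encodes the NF-κB inducing kinase, and Relb were lower when adjusted over the list alone, with log2 fold changes of -0.89 and -1.15. Relb, Nfkb2 and Birc3 also stand in the target list. They are among the 5 pathway members lower at an unadjusted edgeR p under 0.05, so the pathway result is not independent of the target list. Ltbr itself had a log2 fold change of 0.36 (95% interval 0.02 to 0.69, edgeR adjusted p = 0.751) at 74.7 ± 8.81 CPM in control libraries (SD, n = 4). The antigen presentation list was lower with the preset correlation (median -0.28 over 18 genes, camera adjusted p = 0.00134, adjusted p = 0.748 with an estimated correlation). The class I genes H2-K1 (-0.46) and H2-Q7 (-0.60) were lower when adjusted over the list alone, and reads of these close paralogs may be shared. B2m and Tapbp had -0.36 and -0.31 and did not pass. Without control replicate 3 the antigen presentation list had a camera adjusted p of 0.0983. The pathway list had 0.0606 to 0.122 without control replicate 1, 3 or 4 or LTβR-Ig replicate 1 or 3.

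Niche factors were compared next. Il7 was at 196 ± 19.6 CPM in control and 222 ± 39.8 CPM in LTβR-Ig libraries (SD, n = 4 each), with a log2 fold change of 0.18 (SE 0.15, 95% interval -0.15 to 0.52, edgeR adjusted p = 1). Kitl, which encodes stem cell factor, had -0.58 (SE 0.10, edgeR adjusted p = 0.125), was lower in 4 of 4 libraries and was lower when adjusted over the list alone. DESeq2 called Kitl over all genes with an adjusted p of 2.48e-05. Cxcl12, at 16378 ± 2252 CPM in control libraries (SD, n = 4), had 0.22, Csf1 0.07 and Vcam1 0.09, with overlapping groups. Il15, at 32.0 ± 10.2 CPM in control libraries (SD, n = 4), had a 95% interval of -0.59 to 0.59. The niche factor list did not pass (camera adjusted p = 0.477). Its median was 0.09 and its mean -0.09, on opposite sides of 0.

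Markers of the sorted population showed no shift in 1 direction past the threshold (median log2 fold change 0.00 over 24 genes, camera adjusted p = 0.928). Members went both ways: 4 were higher and 3 lower at an unadjusted edgeR p under 0.05, against 544 and 470 of all 16045 genes. The higher 4 were Fbln5 (0.53), Cdh11 (0.34), Ccn1 (1.17) and Gas6 (0.41). The form of fry that allows both directions gave an unadjusted p of 0.00135. Kitl and Snai2, a mesenchymal transcription factor, were lower when adjusted over the list alone, at -0.58 and -0.52. Lepr, at 4305 ± 45.9 CPM in control libraries (SD, n = 4), had -0.14 (95% interval -0.39 to 0.11). Pdgfra had -0.29 (edgeR adjusted p = 0.649) and was lower in 4 of 4 libraries. Ebf3 had -0.11, and Foxc1 had -0.08 with 1 control library at 565 CPM and the others at 277 to 313 CPM; without that library, control replicate 3, Foxc1 had 0.23. Adipocyte lineage genes did not pass as a list (median 0.17 over 27 genes, camera adjusted p = 0.0501). Within it Pparg had 0.08, Cebpa 0.32, Adipoq 0.17 and Lpl 0.08.

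Osteoblast lineage genes were higher as a list with the preset correlation (median log2 fold change 0.41 over 28 genes, camera adjusted p = 7.27e-06), and the call was lost with an estimated one (adjusted p = 0.636 with an estimated correlation). Alpl, the bone alkaline phosphatase gene, was higher when adjusted over the list alone, at 534 ± 93.4 against 276 ± 76.6 CPM (SD, n = 4 each), and DESeq2 called it over all genes (log2 fold change 0.95, edgeR adjusted p = 0.223, DESeq2 adjusted p = 0.00471). The osteoblast transcription factor gene Sp7 had 0.95 and the collagenase gene Mmp13 1.00, and neither passed. Col1a1 had 0.41 and Bglap 0.45, but without LTβR-Ig replicate 3 they had -0.26 and -0.34. Reads of Bglap may be shared with its close paralogs. Runx2 had -0.39, with LTβR-Ig replicate 1 at 7.0 CPM and the other 7 libraries between 120 and 203 CPM.

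Extracellular matrix genes were also higher as a list (median 0.35 over 33 genes, camera adjusted p = 1.4e-05, adjusted p = 0.636 with an estimated correlation). Adjusted over the list alone, Tnc, Col3a1 (0.45), Timp2 (0.38), Mmp14 (0.56) and Fbn1 (0.50) were higher and Thbs2 (-0.79) was lower. Beside both lists, megakaryocyte markers had a median log2 fold change of 0.64 and endothelial markers 0.49.

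**Figure D3:**
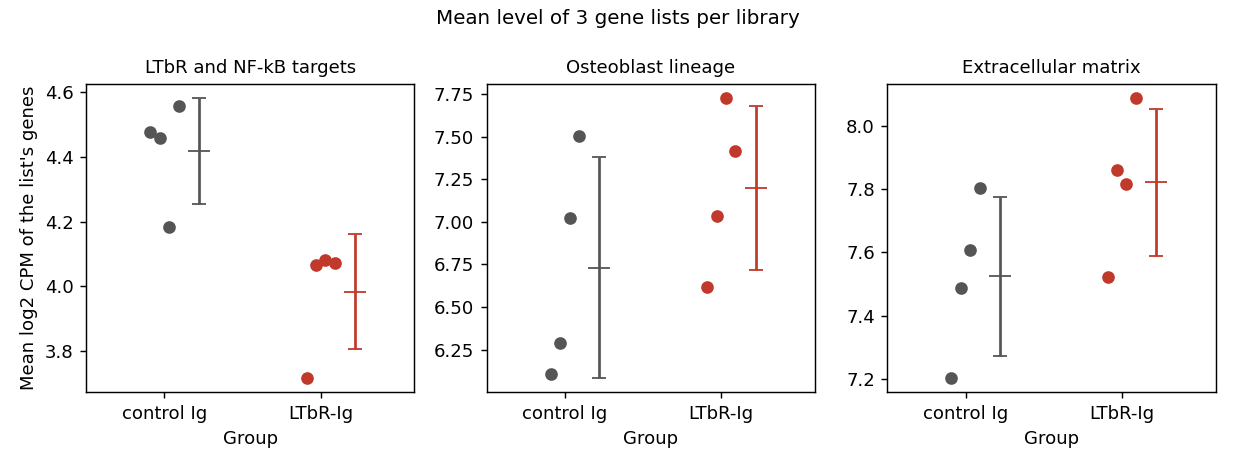
Mean log2 CPM of the genes of 3 lists, with 1 point per library and the group mean with its SD (n = 4) beside the points, on axes that do not start at 0. Target genes had 4.42 ± 0.163 in control and 3.98 ± 0.178 in LTβR-Ig libraries, and osteoblast genes 6.73 ± 0.648 and 7.20 ± 0.481 with overlapping points.

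Another 3 pathway lists passed with the preset correlation and lost the call with an estimated one. TGF-β and BMP response genes were higher (median 0.29 over 19 genes, camera adjusted p = 0.0379, adjusted p = 0.349 with an estimated correlation). Of these, Bmper, a secreted BMP regulator, was higher when adjusted over the list alone (log2 fold change 1.19, edgeR adjusted p = 0.125). Cholesterol biosynthesis genes were higher (median 0.13 over 23 genes, camera adjusted p = 0.0441, adjusted p = 0.668 with an estimated correlation), with Dhcr7 at 1.29 and Hsd17b7 at 0.70. Cytosolic ribosomal protein genes were lower (median -0.13 over 32 genes, camera adjusted p = 0.016, adjusted p = 0.805 with an estimated correlation), with Rps9 at -0.19 and Rpl18 at -0.20. No member of the cholesterol and ribosomal lists passed when adjusted over the list alone by edgeR, where 3 and 0 members had an unadjusted p under 0.05. The TGF-β and BMP list had a camera adjusted p of 0.0591 to 0.125 without control replicate 1 or 2 or LTβR-Ig replicate 2 or 3. The cholesterol list had 0.0884 to 0.254 without control replicate 1 or 4 or LTβR-Ig replicate 1 or 3, and the ribosomal list 0.0799 to 0.534 without control replicate 1 or LTβR-Ig replicate 3 or 4.

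Markers of other cell types were used to look for cells that the gate had left in. Some are also made by LEPR+ cells, such as Vcam1 at 4385 ± 519 CPM in control libraries (SD, n = 4). The shares can therefore partly reflect the sorted cells themselves. The gate removes CD45, Ter119, CD31 and CD144 positive cells. Erythroid markers took 3.65 ± 1.51% of counts in control and 3.24 ± 0.86% in LTβR-Ig libraries (SD, n = 4 each). Megakaryocyte and platelet markers took 0.16 ± 0.113% and 0.245 ± 0.139%, a ratio of 1.53, and endothelial markers 0.0308 ± 0.00946% and 0.0433 ± 0.029%, a ratio of 1.41. The endothelial ratio rested on LTβR-Ig replicate 3, at 0.0852% against 0.0186 to 0.0373% in the other LTβR-Ig libraries, and was 0.952 without it. Without that library the megakaryocyte ratio was 1.13, and the erythroid ratio of 0.888 was 1.09 without control replicate 3. The largest shift by p was that of Schwann and nerve markers, with a ratio of 1.5 (exact two-sided permutation p = 0.0857, adjusted p = 0.914 over 12 lists). None of the 12 shares had an unadjusted p under 0.05. The smallest possible p of 4 against 4 libraries is 0.0286, so after adjustment a share could pass only if at least 7 of the 12 reached it. As gene lists, megakaryocyte markers were higher (median 0.64, camera adjusted p = 0.000282, adjusted p = 0.769 with an estimated correlation), with Gp5 at 1.02 and Itgb3 at 0.66. Neutrophil markers were lower (median -0.19, camera adjusted p = 0.0209, adjusted p = 0.805 with an estimated correlation), with Mmp8 at -1.05 and Mmp9 at -0.90. No single marker of these 2 lists passed when adjusted over the list alone by edgeR, where 0 and 2 members had an unadjusted p under 0.05. The megakaryocyte list had a camera adjusted p of 0.0785 without control replicate 1 and 0.0799 without LTβR-Ig replicate 3. The neutrophil list had 0.0606 to 0.521 without control replicate 1, 3 or 4 or LTβR-Ig replicate 1 or 4.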

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

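Chosen only after the result was seen were the tests of another cell type, of depth, of the marker covariate and of a single library, and that of molecule loss. Other forms of the cell type test were also run before this one was kept: from the slope on marker shares in the 4 controls alone, or the bounds of the shares, plasma cells stayed open for Meox1, and edgeR with the log2 share as a covariate called 5 or 6 of the 6 genes with each share but that of Schwann and nerve markers, where it called 1. The mean level of the target list, with members that go both ways, was -2.65% of control without a covariate (95% interval -29.7 to 24.4%), so it showed no fall to test, and it was set aside after its values were seen. In each group of 4 libraries, a value counted as standing apart when its gap to the nearest other took most of the range, which chance gives for about 1 in 20 groups. Of 142 gene and group pairs 6 stood apart, and of 34 pairs of marker shares and library measures 2. Foxc1 was at 565 CPM in control replicate 3 against 277 to 313 CPM in the other controls. Nfkb2 was at 18.1 CPM in control replicate 1 against 13.7 to 14.3 CPM. H2-K1 was at 1428 CPM in LTβR-Ig replicate 1 against 1533 to 1548 CPM. Ebp, a cholesterol synthesis gene, was at 115 CPM in LTβR-Ig replicate 3 against 132 CPM in the others. Bmper was at 34.7 CPM in control replicate 4 against 29.4 to 30.1 CPM. The platelet gene Gp5 was at 13.8 CPM in control replicate 4 against 4.09 to 4.80 CPM, and endothelial markers took 0.0449% of counts in that library against 0.0248 to 0.0275%. LTβR-Ig replicate 2 had 18383 genes detected against 19529 to 19616.

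C3, Ager, Dclk1, Angptl1, Meox1 and Gm37802 and the LTβR target list were lower with LTβR-Ig. Of 35 splits of the 8 libraries, 1, the real one, gave 6 genes, against at most 2 in the others. The real split was also the 1 of 35 with a camera p for the target list as small as 2.88e-13, against 3.77e-05 for the best other split. A share of 1 of 35 is the smallest that this test can give, so regrouping by chance was not excluded. The other splits mix treated and control libraries, so a real effect would add to their spread. Depth alone is argued against, since 6 of the 6 genes were still called after thinning to the smallest library. With each of 12 marker shares as a covariate every gene stayed lower, with upper 95% bounds at or below -31.7% of the control mean. The target list stayed lower by -40 to -48.3% in its median level (upper bounds at or below -16.2%). Its mean log2 level had upper bounds at or below -0.0267. No share took the whole change away, but this does not decide whether fewer cells of a listed type were the whole source. Some markers are also made by LEPR+ cells. Other forms of the test did not all give the same answer, with plasma cells open for Meox1. With the Schwann and nerve share edgeR called 1 of the 6 genes, against 5 or 6 with each other share. That share was itself higher, not lower, with LTβR-Ig (ratio 1.5). A candidate explanation is an effect of the decoy on LEPR+ cells. Fewer cells of a listed type remain possible. A shift among LEPR+ subsets or an unlisted cell type also stays open and was not tested.

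The osteoblast list was higher with the preset correlation, with a median log2 fold change of 0.41. Regrouping by chance was not excluded: 8 of 35 splits gave a list p at or below the real 4.41e-07, down to 4.6e-20. Of the list counts, 13 of 35 splits called as many as the real 10 lists, up to 15, so the number of lists called does not by itself set the treatment apart from other groupings. Varying content of megakaryocytes and vessel cells and the weight of a single library cannot be told apart from a treatment effect: the median was 0.265 with the marker level as a covariate and 0.248 without LTβR-Ig replicate 3, both above 0.205, which is 50% of the real median, by less than their spread over members, while it was 0.641 without LTβR-Ig replicate 1 and 0.959 without control replicate 4. An effect of the decoy on bone-forming cells may exist but was not separable here from differences in osteoblast content between libraries.

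Some well expressed genes were near 0 in single libraries. Of 7095 genes with a median of at least 20 CPM, immunoglobulin genes left out, 56 had a library under 10% of the median, with 38 such values in each group; Adam10 was at 9.51 and 6.48 CPM in control replicates 3 and 4 and at 232 to 316 CPM in the other libraries. Chance loss of molecules at low input is argued against for genes at 100 CPM and above, of which 0.806% had such a library, 5.09 times the share at 50 to 100 CPM (95% interval 1.44 to 27.4), but cannot be told apart for genes at 20 to 100 CPM, since the share fell with level, from 6.26% at 5 to 10 CPM and 1.53% at 10 to 20 CPM to 1.14% at 20 to 50 CPM and 0.158% at 50 to 100 CPM, the last 0.103 of that at 10 to 20 CPM. Reads shared with overlapping genes cannot be told apart as a source: 66.7% of the genes overlapped another annotated gene against a median of 55.6% in level-matched lists, of which 7.17% were as high. No biological explanation was tested, since the values fall on both groups alike.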

How the results depend on the processing

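C3 was called in every setting run on genes. The thinned libraries, the marker covariate, the strict filter with the block, the fit without the libraries at the ends of the first principal component and the estimated correlations with other fits were chosen after seeing the data. The main count of genes changed by LTβR-Ig was 6 (0 higher, 6 lower). It was 8 (2 higher, 6 lower) with DESeq2 size factors in edgeR, with no filter and with thinned libraries, 6 with upper-quartile factors and 5 with the covariate. It was 338 (167 higher, 171 lower) with DESeq2, 17 (3 and 14) with limma-voom and 22 (5 and 17) with the strict filter, which tests fewer genes; for the other shifts the cause was not tested. Without the libraries at the ends of the first principal component it was 1 (0 higher, 1 lower). Leaving out each library gave 2 to 9 genes, with 0 to 2 higher and 2 to 7 lower. The count was 2 without control replicate 3 and 9 without LTβR-Ig replicate 4. The calls lost without single libraries were of Gm37802, Meox1, Angptl1 and Dclk1. Other genes were gained, so a similar count does not mean the same genes. Among those gained, Mier3, Gm15564 and Stk38l were near 0 in 3 libraries of a group. Each was called when that group's other library was left out. With the replicate number as a block the count was 1 (0 higher, 1 lower), and 18 (5 and 13) with the strict filter and the block. The series' design text speaks of 4 pairs without saying what a pair shares or whether the numbers mark it. Deviations of same-numbered libraries correlated at 0.075, 0.03, 0.045 and 0.00013, all under 0.1, so the numbers were not taken as pairs. As a hint from the data, not every library correlated best with its own number. The same-numbered values were all above 0, against -0.087 to 0.079 for the others, so pairing by number is not ruled out. Mean osteoblast levels also ran in a similar order by number. They were 6.109, 6.29, 7.021 and 7.502 log2 CPM in control replicates 1 to 4. In LTβR-Ig replicates 1 to 4 they were 6.615, 7.035, 7.728 and 7.417. With the block the camera adjusted p was 8.27e-08 for the osteoblast list and 4.57e-06 for the matrix list. With an estimated correlation as well it was 0.453 and 0.172. The exact sign-flip test of 4 pairs cannot give a p under 0.125.

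Of the 33 gene lists 10 were called, against 1 with an estimated correlation and 2 with fry. Leaving out each library gave 4 to 13 lists, with 4 without control replicate 1. With an estimated correlation the count was 0 under the replicate block, 0 without the libraries at the ends of the first principal component and 0 to 1 without each library. The LTβR and NF-κB target list passed with the preset correlation in all settings run (adjusted p 3.81e-13 to 2.62e-08 without each library). With an estimated correlation its adjusted p was 0.126 under the replicate block, 0.246 without the libraries at the ends of the first principal component, and 0.0194 to 0.0567 without each library, the last without LTβR-Ig replicate 2; the cause was not tested. Il7 kept its direction in all settings run (log2 fold change 0.12 to 0.34).

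Some named genes changed sign, and none of them was called with all libraries. Without the libraries at the ends of the first principal component Csf1 had -0.0698, Foxc1 0.314 and Cebpa -0.0267. Il15 had 0.00205 with no filter, 0.0381 under the replicate block, 0.0338 with the strict filter and block and 0.00253 when thinned, and Foxc1 0.00351 with limma-voom. Leaving out each library, Csf1 ranged from -0.00632 to 0.15, Il15 from -0.19 to 0.17, Foxc1 from -0.33 to 0.23, Pparg from -0.0200 to 0.18, Runx2 from -0.73 to 0.00681, Col1a1 from -0.26 to 0.98 and Bglap from -0.34 to 1.22. Of the values of named genes under other settings, 722 kept direction and side of the threshold, 37 newly passed it, 12 no longer passed it and 8 changed sign. Without a library these were 541, 1, 12 and 14. Thinning to the smallest total kept all 6 calls.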

Other observations

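All families in this part were chosen and tested after their members had been seen, except the markers tested for Kit. Kit itself was chosen after its values were seen. Only the prediction for its marker test was written before the result of that test. Complement genes other than C3 were also lower in places. C1ra, which encodes a protease of the classical pathway, had a log2 fold change of -0.75 and C1s1 -0.89, both lower in 4 of 4 libraries and lower when adjusted over the family alone. Neither passed over all genes by edgeR (adjusted p = 0.153 and 0.166), and both passed by DESeq2. Cfb had -0.59 and C4b -0.34. The hypothesis that complement genes fell as a family gave a camera p of 0.00469 with an estimated correlation over 24 genes, but 0.0791 without C3, so the family beyond C3 stays undecided. In the Serpina3 cluster, 5 of 6 tested genes had a lower estimate, with Serpina3g at -1.52, Serpina3f at -1.51 and Serpina3c at -0.92. Its camera p with an estimated correlation was 0.00605, on genes picked because members were lower, and close paralogs may share reads.

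Among genes with higher estimates, Tubb6 had a log2 fold change of 0.95, Tubb2a 0.72 and Tuba1c 0.36, each higher in 4 of 4 libraries, none past the threshold over all genes by edgeR and all past it by DESeq2. The tubulin genes gave a camera p of 0.0454 with an estimated correlation over 15 genes, on a family picked after seeing them. Kit, the receptor for stem cell factor, was at 53.3 ± 10.4 CPM in control and 120.5 ± 21.1 CPM in LTβR-Ig libraries (SD, n = 4 each). Its log2 fold change was 1.18 with an edgeR adjusted p of 0.0865, and it passed by DESeq2 and under the strict filter. Whether a larger content of haematopoietic progenitors or mast cells was its source was not decided. Their 14 markers had a median of -0.32, with a bootstrap interval of -0.84 to 0.08 over markers, below 0.588, which is 50% of the change of Kit. These markers were thus not higher as a group. The interval takes markers as independent and holds no spread between libraries, so it cannot settle the question. Lrp1, an endocytic receptor gene, had 0.91 and Clec11a, an osteogenic growth factor gene, 0.81, both higher in 4 of 4 libraries (edgeR adjusted p = 0.0746 and 0.146). Both passed by DESeq2, and Lrp1 also under the strict filter. The receptor genes Calcrl (-1.10) and Edar (-1.36) were lower in 4 of 4 libraries with edgeR adjusted p of 0.0627 and 0.0859. Both passed by DESeq2 and under the strict filter, and Calcrl also with limma-voom.

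The other lists did not pass with the preset correlation. Camera adjusted p was 0.0561 for immediate early and stress genes (median 0.33) and 0.0685 for cell cycle genes (median -0.15). It was 0.131 for Wnt response, 0.137 for glucocorticoid response and 0.139 for the unfolded protein response. For chondrocyte genes it was 0.279, for mitochondrially encoded transcripts 0.277, for hypoxia and glycolysis 0.771 and for nuclear oxidative phosphorylation genes 0.985. The interferon response list had 0.771, with a median of 0.07 and a lower direction in the test. Of the other cell types, Schwann and nerve markers had 0.119, macrophage markers 0.204, T and NK cell markers 0.204, endothelial markers 0.208, erythroid markers 0.403, B cell markers 0.466, fibroblast markers 0.619, smooth muscle and pericyte markers 0.665, plasma cell markers 0.767 and skeletal muscle markers 0.985. Median and mean differed in sign for the LEPR+, plasma cell, fibroblast, Schwann and skeletal muscle lists.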
